A study of Mus musculus with 6 samples.

How the data were processed

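RNA from 3 mouse endothelial cell lines derived from embryonic stem cells was measured on Affymetrix Mouse Gene 1.0 ST arrays, with 2 arrays for each line. Per the labels' protocols, 50000 cells were seeded per square centimetre, cultured for 72 h and starved for 18 to 20 h in medium with 1% albumin, and 150 ng of RNA was amplified for each array. Per the series' design text, 2 RNA extractions were processed for each line. The arrays were grouped by the line named in their titles (N, VE or VE+N), and every array was used.

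The log2 values were made by the authors with the RMA algorithm in Partek 6.3, per the submitters' processing notes. RMA corrects background, normalizes probes by quantiles and summarizes each probe set. That the scale is log2 was read from the range of the values, and no further normalization was applied in the main analysis. Per the series' design text, the authors called genes by analysis of variance at a fold over 2 and p of 0.05.

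Of 35556 probe sets, 21789 carried 1 gene symbol, 12146 none and 1621 several. Symbols were brought up to date through Entrez identifiers (21698), accessions (3) or kept as annotated (88). Of the 1001 genes with several probe sets, the probe set with the highest mean over the 6 arrays was used, which left 19936 genes. No filter on signal was applied.

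Differences between lines were tested with limma 3.58.1 in R 4.3.3, in a model of line means over all 6 arrays with moderated variances (3 residual and 4.89 prior degrees of freedom). P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called at adjusted p below 0.05. Fold calls also needed a change over 2-fold. The comparisons were VE minus N, VE+N minus N and VE+N minus VE. Values after ± are the SE of a log2 difference or, where stated, the SD over the 2 arrays.

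Gene lists (30 lists with 958 members) were tested with limma's camera at a correlation of 0.01, adjusted over the lists in each comparison, and again with an estimated correlation. Of the members 907 were measured. The result of 1 list, which was called in no comparison, is not reported here. List members were also counted with the adjustment made over the list alone. The grouping, the tests of genes and lists in the 3 comparisons, the lists, the rule for naming genes and all alternatives except 1 were set before the data were examined. Leaving out every gene of chromosomes 4, 10 and 18 was added after, as were the search for runs of neighbouring genes, the tests of probe sets without a single symbol and the tests of explanations in the closing section.

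Genes named in the text are Cdh2 and Cdh5, the 10 largest rises and 10 largest falls among called genes in each comparison, up to 4 called members of a list with the largest change, and 5 genes for each class of VE+N position. Predicted genes, clones, pseudogenes and small RNAs were left out. Genes named outside this rule are stated to be so.

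The overlap of calls that share a line was set beside 100 simulations of unchanged lines. Runs of neighbouring genes were sought in gene order on GRCm38.p6, used for order only because no assembly is named for the values, with 200 shuffles. The analysis was tested on simulated data: over 20 simulations it recovered 99.8% of genes raised by 1 log2 unit, 98.9% of those lowered by 1 and 40.5% of those raised by 0.5, with 6.82% false calls. A cell cycle list shifted by 0.3 was called in 20 of 20 simulations, and a block of 60 genes raised by 0.5 among 300 was found in 18 of 20. The list simulations drew each gene independently, while the estimated correlation of the cell cycle list in the data was 0.258. They thus do not test calls of lists with correlated genes.

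The alternatives were fits on 4 arrays only, with a replicate block, array weights or a trended robust prior, median centring or quantile normalization again, removal of the dimmest 25% or 50% of genes, all probe sets or their mean, the methods' analysis of variance, treat against 1.5-fold, each array left out in turn, and fry for the lists. Probe sets with no symbol or several were left out of the gene tests.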

Results

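Gene expression was measured in 3 mouse endothelial cell lines derived from embryonic stem cells. The labels name the lines by the cadherin they express: N-cadherin, VE-cadherin, or both. N-cadherin (Cdh2) and VE-cadherin (Cdh5) are calcium-dependent adhesion molecules at the contacts between cells. The cells were seeded at 50000 per square centimetre, kept for 72 h so that they stayed confluent, and held for 18 to 20 h in medium with 1% albumin before RNA was taken. Each line was hybridised on 2 whole-transcript arrays, 6 arrays in all, and each array gave log2 values for 35556 probe sets. The median probe set lay between 4.85 and 4.91 on the 6 arrays. Arrays have no read depth, and their number limits the precision here. In 48 of the 60 largest rises and falls named below, the lower of the lines compared lay under its median gene. Signal over background was not examined there, so the sizes and order of these changes are approximate.

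The arrays grouped by line. The SD of the difference between the 2 arrays of a line, across 19936 genes, was 0.185 in the N-labelled, 0.196 in the VE-labelled and 0.244 in the VE+N-labelled line. Between arrays of different lines it ran from 0.399 to 0.559. The first principal component held 57.7% of the variance and set the N-labelled arrays apart from the other 4, and the second, with 29.0%, set the VE-labelled arrays apart from the VE+N-labelled ones. The series text speaks of separate RNA extractions and the titles of biological replicates, and no source used here says that the extracts came from separate cultures. The p-values therefore measure the spread between extracts of 1 line per cadherin state, and a difference that belongs to the cadherin is not separable from any other difference between these lines.

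The cadherin genes themselves were examined first. Cdh2 followed the labels in part: its mean log2 signal was 7.67 ± 0.0120 (SD, n = 2) in the N-labelled line, 6.69 ± 0.0105 in the VE+N-labelled line and 5.86 ± 0.0933 in the VE-labelled line. It was lower in the VE-labelled than in the N-labelled line by a log2 difference of −1.80 ± 0.0992 (SE), adjusted p = 1.87e-05, and the VE+N-labelled line lay between them, at −0.97 from the N-labelled line (adjusted p = 0.000315) and 0.83 above the VE-labelled line (adjusted p = 0.00155). No difference in Cdh5 passed the main test. Its mean signal was 7.28 ± 0.0254 in the N-labelled, 6.94 ± 0.156 in the VE-labelled and 7.10 ± 0.0832 in the VE+N-labelled line, and the differences of −0.34 for VE against N (adjusted p = 0.0917), −0.17 for VE+N against N (adjusted p = 0.366) and 0.16 for VE+N against VE (adjusted p = 0.462) did not pass. Under 5 of 20 alternatives the VE versus N difference passed, each time lower in the VE-labelled line and so against the labels, at −0.44 with median centring and −0.39 with quantile normalization again. The VE+N versus VE difference moved with single arrays: it was 0.27 without VE replicate 1, 0.05 without VE replicate 2 and 0.10 without VE+N replicate 2, and VE+N versus N was −0.12 without VE+N replicate 1, none passing. The single Cdh5 probe set thus does not bear out the VE-cadherin part of the labels, and its probe positions are not known here. Lines are called by their label throughout, and every direction below rests on those labels. None of the gene list calls below held with a correlation between genes estimated from the arrays. That form of camera also rests its test on the 3 residual degrees of freedom, so a lost call is not a sign of correlation alone. In VE+N versus VE, the FGF pathway list had an estimated correlation of −0.0233, below the preset 0.01. Its unadjusted camera p still moved from 1.46e-07 to 0.0091.

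**Figure D1:**
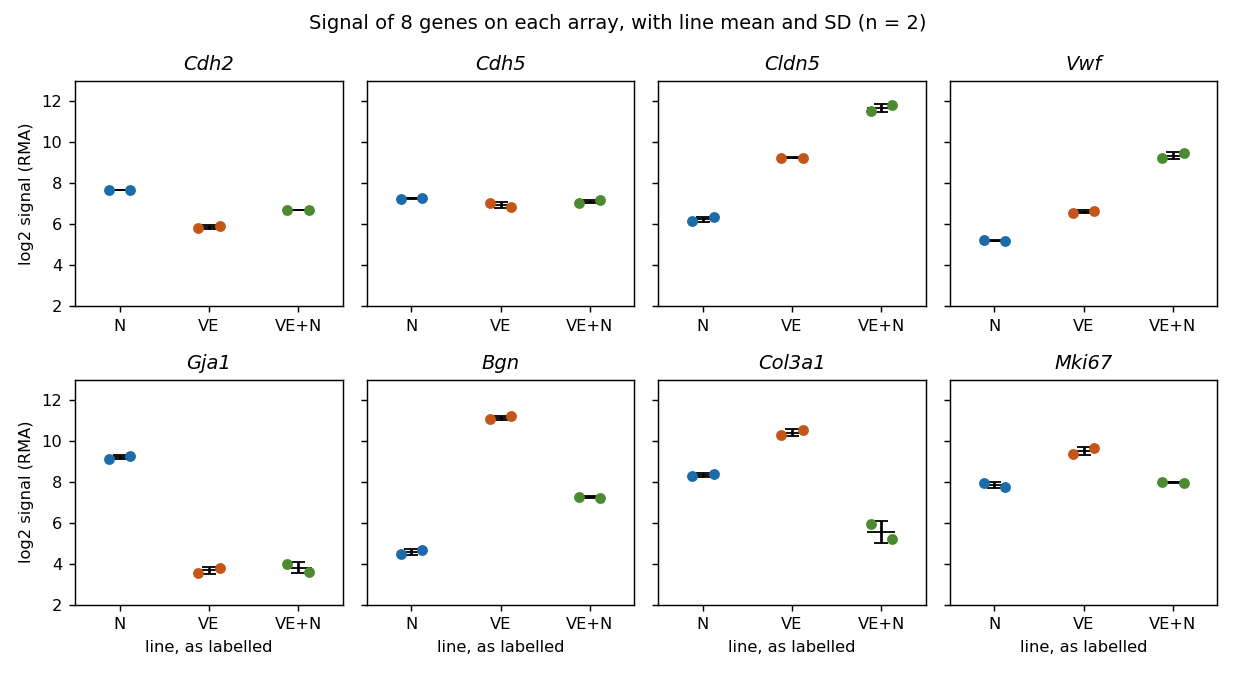
Log2 signal (y axis, RMA) of 8 genes on each of the 6 arrays (coloured points), with the mean of each line (horizontal bar) and its SD (whiskers, n = 2), by line as labelled (x axis). Cdh2 was highest in the N-labelled line at 7.67, Cdh5 lay between 6.94 and 7.28 in all 3 lines, and Cldn5 was 6.24, 9.26 and 11.68 in the N-, VE- and VE+N-labelled lines.

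The first comparison asked how endothelial cells labelled as expressing VE-cadherin differ from those labelled as expressing N-cadherin. In the VE-labelled line, some genes of the extracellular matrix were far higher, among them biglycan (Bgn), a small proteoglycan, by 6.56 ± 0.112 (SE) log2 units, and dermatopontin (Dpt) by 6.12 ± 0.125. The tight junction gene Cldn5 was higher by 3.02 ± 0.125. Of 32 tight junction genes 4 rose and 2 fell, 4 and 4 adjusted over the list alone (camera adjusted p = 0.961). The gap junction gene Gja1 was lower by a log2 difference of −5.52 ± 0.149, from 9.20 ± 0.0912 (SD, n = 2) in the N-labelled to 3.68 ± 0.153 in the VE-labelled line, and Pmepa1, an inhibitor of Smad signalling, by −5.41 ± 0.153. Nearly all measured cell cycle genes rose. In limma, 3079 of 19936 genes passed adjusted p 0.05, 1686 higher and 1393 lower in the VE-labelled line, and 760 of them differed over 2-fold (515 higher, 245 lower). Without N replicate 1, N replicate 2, VE replicate 1 or VE replicate 2 the count was 1741, 1739, 1741 or 1688. The methods' analysis of variance gave 1276 calls with Benjamini-Hochberg and 4678 without adjustment, 751 of the latter over 2-fold. Treat against 1.5-fold gave 590.

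The other largest rises in the VE-labelled line were Gatm at 5.89 ± 0.145, an enzyme of creatine synthesis, the apelin receptor Aplnr at 5.68 ± 0.180, the fatty acid binding protein Fabp4 at 5.12, Rassf9 at 4.76 ± 0.201, the scavenger receptor Stab2 at 4.47 ± 0.116 and the inflammatory protease Casp1 at 4.22 ± 0.145. Their adjusted p-values lay between 2.95e-07 and 5.09e-06. The chemokine Cxcl15 and the acute phase gene Saa3 rose by 4.9 ± 0.338 and 4.32 ± 0.432, with a wider spread between the VE-labelled arrays (SD 0.881 and 1.15). The largest falls after Gja1 and Pmepa1 were in Entpd1, an enzyme that breaks down extracellular ATP (−4.86 ± 0.115), Pon3 (−4.53 ± 0.188), Tspan13 (−4.53 ± 0.107), Taf9b (−4.52 ± 0.137), Igfbp5 (−4.50 ± 0.12), Cpne8 (−4.48 ± 0.0986), the imprinted gene Mest (−4.39 ± 0.103) and Nostrin, which binds endothelial nitric oxide synthase (−4.35 ± 0.127). Their adjusted p-values lay between 3.51e-07 and 4.79e-06.

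Of 39 measured cell cycle genes 36 rose and 0 fell, 36 and 0 adjusted over the list alone, with a median log2 difference of 0.92. The camera test gave adjusted p = 1.65e-26, and adjusted p = 0.441 with an estimated correlation. The proliferation marker Mki67 rose by 1.68 ± 0.128, cyclin A2 (Ccna2) by 1.55 ± 0.139 and the mitotic motor Kif11 by 1.53 ± 0.114. Of 35 mesenchymal genes 19 rose, 1 fell and 15 did not pass, 20 and 2 adjusted over the list alone, with a median of 0.78 (camera adjusted p = 4.54e-11, and adjusted p = 0.352 with an estimated correlation). Besides Bgn, these included the collagens Col1a1 at 3.40 ± 0.138 and Col6a3 at 2.77 ± 0.111 and decorin (Dcn) at 3.07 ± 0.235. The member that fell was Fap, a protease of activated fibroblasts, at −1.64, named after its value was seen. Beside this list, 2 of 24 mural cell genes rose and 3 fell, the same counts adjusted over the list alone (camera adjusted p = 0.217), with the potassium channel subunit gene Abcc9 at −1.99 ± 0.118 and the smooth muscle actin gene Acta2 at −1.07 ± 0.158.

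Hypoxia and glycolysis genes were also higher as a group. Of 31 members 13 rose and 1 fell, again 13 and 1 adjusted over the list alone, with a camera adjusted p = 0.00363 (adjusted p = 0.611 with an estimated correlation). The angiogenic factor Vegfa rose by 1.24 ± 0.108, Ankrd37 by 1.22 ± 0.126 and the carbonic anhydrase Car9 by 1.02 ± 0.169, while adrenomedullin (Adm) fell by 0.96 ± 0.149. Of 22 YAP/TAZ targets 7 rose and 2 fell, and 12 and 3 adjusted over the list alone (camera adjusted p = 0.0256, and adjusted p = 0.481 with an estimated correlation), with Gadd45b at 1.78 ± 0.118 and the receptor kinase Axl at 1.49 ± 0.138. That call was lost without the dimmest 25% of genes (adjusted p = 0.0793), with a list median of 0.365 in both tests. Of 31 genes of inflammation and leukocyte adhesion 10 rose and 4 fell, and 12 and 5 adjusted over the list alone (camera adjusted p = 0.0277, and adjusted p = 0.589 with an estimated correlation). The neutrophil chemokine Cxcl5 rose by 2.91 ± 0.217, lipocalin 2 (Lcn2) by 2.65 ± 0.393, Il33 by 2.63 ± 0.248 and the prostaglandin synthase Ptgs2 by 2.60 ± 0.259. The VE-labelled arrays spread more widely in Cxcl5 and Lcn2 (SD 0.528 and 1.04) than in Il33 and Ptgs2 (SD 0.0806 and 0.0881). The inflammation call was lost without VE replicate 1 (adjusted p = 0.0638) and without the dimmest 25% of genes (adjusted p = 0.0793).

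Genes of the angiogenic tip cell and VEGF pathway were lower as a group in the VE-labelled line: 6 of 36 rose and 15 fell, 6 and 15 adjusted over the list alone (camera adjusted p = 0.0123, and adjusted p = 0.589 with an estimated correlation). The guidance receptor Robo1 fell by 4.25 ± 0.0959, placental growth factor (Pgf) by 2.84 ± 0.179 and Igfbp3 by 2.07 ± 0.280, while Sema3c rose by 2.18 ± 0.162. Arterial and Notch genes were lower too, with 5 of 30 up and 10 down, 5 and 13 adjusted over the list alone (camera adjusted p = 0.0180, and adjusted p = 0.481 with an estimated correlation). Mfng, which modifies Notch receptors, fell by 2.58 ± 0.140, the chemokine receptor Cxcr4 differed by −2.06 ± 0.131 and the Notch ligand Dll4 by −1.48 ± 0.141, while the Cxcr4 ligand Cxcl12 rose by 1.90 ± 0.112. The arterial call was lost with median centring of the arrays (adjusted p = 0.0641) and without the dimmest 25% of genes (adjusted p = 0.0793). Its list median, −0.211 in the main test, was −0.319 and −0.211 there. The other 23 of 30 lists were not called, the lowest of their adjusted p-values being 0.0665, and in 7 of them the median, the mean and the test differed in sign. Among 42 endothelial identity genes 6 rose and 12 fell, 6 and 15 adjusted over the list alone (camera adjusted p = 0.0880): the matrix protein Mmrn2 at 2.44 ± 0.136, Adgrf5 at 1.41 ± 0.101, von Willebrand factor (Vwf) at 1.41 ± 0.116 and the phosphatase Ptprb, a partner of VE-cadherin, at 1.31 ± 0.112 were the largest changes.

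Median centring lowered every VE minus N difference by 0.108, so that the median over all genes moved from −0.0215 to −0.130. The split of 54.8% higher among the called genes then became 34.9% higher, so the balance of small rises and falls rests on the scaling. Among genes over 2-fold the share of higher calls was 67.8%, and 58.7% with median centring.

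The second comparison set the line labelled as expressing both cadherins against the N-labelled line. The VE+N-labelled line had far more of the tight junction gene Cldn5, by 5.44 ± 0.125 (SE) log2 units, from 6.24 ± 0.141 (SD, n = 2) to 11.68 ± 0.186, and of Vwf, by 4.13 ± 0.116. Of 32 tight junction genes 4 rose and 3 fell, 5 and 3 adjusted over the list alone (camera adjusted p = 0.453). Igfbp5 fell by 6.03 ± 0.12, Robo1 by 5.59 ± 0.0959 and the pericyte growth factor receptor Pdgfrb by 4.85 ± 0.140. Genes of cholesterol synthesis, the interferon response and the tip cell pathway were lower as groups. In limma, 3802 of 19936 genes passed adjusted p 0.05, 2025 higher and 1777 lower in the VE+N-labelled line, and 918 differed over 2-fold (488 higher, 430 lower). Without N replicate 1 or N replicate 2 the count was 2243 or 2263, with the methods' analysis of variance and Benjamini-Hochberg it was 1867, and with treat 795.

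The largest rises were in Gatm (6.24 ± 0.145), Rassf9 (5.98 ± 0.201), the decoy receptor Il13ra2 (5.79 ± 0.163), the urea transporter Slc14a1 (5.48 ± 0.145), the retinol binding protein Rbp2 (5.45 ± 0.104) and Cldn5. They were followed by Aplnr (5.15 ± 0.180), the matrix protein Prelp (5.05 ± 0.113), Rp1 (4.93 ± 0.216) and Casp1 (4.69 ± 0.145). Their adjusted p-values lay between 1.99e-07 and 3.62e-06. Next to Igfbp5 and Robo1, the potassium channel Kcnj2 fell by 5.59 ± 0.125, Pmepa1 by 5.47 ± 0.153, Gja1 by 5.40 ± 0.149, Tspan13 by 4.83 ± 0.107 and Nostrin by 4.82 ± 0.127. The near-identical immune receptor genes Lilrb4a and Lilr4b were also among the largest falls, at −5.27 ± 0.208 and −4.81 ± 0.158, and their probe sets cannot be assigned to 1 copy with certainty.

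Of 42 endothelial identity genes 15 rose and 7 fell in the VE+N-labelled line, 19 and 7 adjusted over the list alone (camera adjusted p = 0.0453, and adjusted p = 0.518 with an estimated correlation). After Vwf, Mmrn2 rose by 3.37 ± 0.136, Ptprb by 2.14 ± 0.112 and Adgrf5 by 1.58 ± 0.101. This call was lost without VE+N replicate 2 (adjusted p = 0.12), without VE replicate 1 or VE replicate 2 (adjusted p = 0.0520 each) and without the dimmest 25% of genes (adjusted p = 0.0852). Of 36 tip cell and VEGF pathway genes 4 rose and 20 fell, 5 and 20 adjusted over the list alone, with a median of −0.69 (camera adjusted p = 3.42e-07, and adjusted p = 0.416 with an estimated correlation). Igfbp3 fell by 4.22 ± 0.280, Pgf by 3.21 ± 0.179 and Dll4 by 2.86 ± 0.141. Arterial and Notch genes gave 4 up and 12 down of 30, and 4 and 13 adjusted over the list alone (camera adjusted p = 6.66e-05, and adjusted p = 0.416 with an estimated correlation). Mfng fell by 3.19 ± 0.140, the Notch target Nrarp by 2.40 ± 0.12 and Cxcr4 by 2.10 ± 0.131.

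Cholesterol synthesis genes moved 1 way: 0 of 20 rose and 12 fell, 0 and 14 adjusted over the list alone, with a median of −0.78 (camera adjusted p = 3.39e-08, and adjusted p = 0.416 with an estimated correlation). Insig1, a sterol-regulated inhibitor of the pathway, fell by 1.74 ± 0.107, and the enzyme genes Lss, Cyp51 and Dhcr7 by 1.20 ± 0.130, 1.11 ± 0.175 and 1.08 ± 0.115. Of 30 interferon response genes 2 rose and 19 fell, 2 and 20 adjusted over the list alone, with a median of −0.52 (camera adjusted p = 1.82e-07, and adjusted p = 0.472 with an estimated correlation). The antiviral genes Rsad2, Oasl2 and Oasl1 fell by 2.58 ± 0.132, 1.98 ± 0.162 and 1.82 ± 0.157. Of 33 FGF pathway genes 7 rose and 14 fell, 8 and 15 adjusted over the list alone (camera adjusted p = 0.0430, and adjusted p = 0.416 with an estimated correlation). The transcription factor Etv1 fell by 2.72 ± 0.126, and the feedback phosphatases Dusp6 and Dusp4 and the inhibitor Spry4 by 1.99 ± 0.129, 1.92 ± 0.130 and 1.89 ± 0.122. The FGF call was lost with median centring (adjusted p = 0.0519), with repeated quantile normalization (adjusted p = 0.0556), without the dimmest 25% of genes (adjusted p = 0.0530) and without VE+N replicate 1 (adjusted p = 0.0573).

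Mesenchymal genes went mainly down against the N-labelled line, with 4 of 35 up and 13 down, 4 and 16 adjusted over the list alone (camera adjusted p = 0.000982, and adjusted p = 0.416 with an estimated correlation). Col3a1 fell by 2.77 ± 0.222 and periostin (Postn) by 2.5 ± 0.135, while Col5a2 rose by 2.72 ± 0.111 and Bgn by 2.67 ± 0.112. Mural cell genes gave 1 up and 7 down of 24, the same adjusted over the list alone (camera adjusted p = 0.0148, and adjusted p = 0.472 with an estimated correlation), with Pdgfrb as above, Acta2 at −2.27 ± 0.158, Notch3 at −2.13 ± 0.106 and Abcc9 at −1.98 ± 0.118. Markers of cardiac and skeletal muscle gave 0 up and 5 down of 26, the same adjusted over the list alone (camera adjusted p = 0.0318, and adjusted p = 0.518 with an estimated correlation). The troponin gene Tnnt2 fell by 1.05 ± 0.0966 and the transcription factor gene Mef2c, which endothelial cells also express, by 0.83 ± 0.0994. The mural and muscle calls were lost without VE+N replicate 2 (adjusted p = 0.136 and 0.282). Of 52 axon guidance and Eph genes 8 rose and 15 fell, the same adjusted over the list alone (camera adjusted p = 0.0467, and adjusted p = 0.518 with an estimated correlation). Sema3d rose by 2.95 ± 0.131, and Efnb1 and Plxnb1 fell by 2.23 ± 0.0994 and 1.96 ± 0.130. The axon guidance call was lost under both other scalings (adjusted p = 0.0539 and 0.0737), without VE+N replicate 2 (adjusted p = 0.257), without VE replicate 1 or VE replicate 2 (adjusted p = 0.0520 each) and without the dimmest 25% of genes (adjusted p = 0.0637).

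The other 20 lists were not called, the lowest adjusted p being 0.0828, and in 5 of them the median, the mean and the test differed in sign. Cell cycle genes, which rose in the VE-labelled line, gave 2 up and 6 down of 39 here, the same adjusted over the list alone (camera adjusted p = 0.111). Genes of inflammation gave 4 up and 6 down of 31, the same adjusted over the list alone (camera adjusted p = 0.593), with Il33 at 3.70 ± 0.248 and the monocyte chemokine Ccl2 at −2.51 ± 0.164. Hypoxia and glycolysis genes gave 5 up and 12 down of 31, and 7 and 14 adjusted over the list alone (camera adjusted p = 0.0953). Of 22 YAP/TAZ targets 6 rose and 7 fell, the same adjusted over the list alone (camera adjusted p = 0.593), with the clotting initiator F3 at −2.17 ± 0.143.

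The third comparison set the line labelled as expressing both cadherins against the VE-labelled line, and single matrix genes again stood out, now as falls. Dpt was lower in the VE+N-labelled line by a log2 difference of −6.78 ± 0.125 (SE), from 9.71 ± 0.109 (SD, n = 2) to 2.92 ± 0.0279, and the collagen Col3a1 by −4.84 ± 0.222. Cell cycle genes fell almost without exception. Of 42 endothelial identity genes 14 rose, among them Vwf by 2.73 ± 0.116, and the tight junction gene Cldn5 rose by 2.42 ± 0.125. Of 32 tight junction genes 3 rose and 0 fell, 4 and 0 adjusted over the list alone (camera adjusted p = 0.218). In limma, 2020 of 19936 genes passed adjusted p 0.05, 855 higher and 1165 lower in the VE+N-labelled line, and 502 differed over 2-fold, 109 higher and 393 lower. Without VE replicate 1, VE replicate 2 or VE+N replicate 2 the count was 975, 966 or 1219. The methods' analysis of variance gave 311 calls with Benjamini-Hochberg, 138 of them over 2-fold, and 3996 without adjustment, 493 of these over 2-fold. Treat gave 334, all over 2-fold, and testing all probe sets 1117.

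The largest rises were in Rbp2 (5.13 ± 0.104), in both subunits of the nitric oxide receptor guanylate cyclase, Gucy1b1 (3.23 ± 0.129) and Gucy1a1 (2.47 ± 0.102), and in Slc14a1 (3.17 ± 0.145). The neuropeptide Nts rose by 3.15 ± 0.112, the integrin Itga8 by 2.98 ± 0.172, Rasd2 by 2.48 ± 0.106 and Gsta3, which has close paralogs, by 2.54 ± 0.193. Their adjusted p-values lay between 4.09e-07 and 0.000170. The largest falls after Dpt were in ceruloplasmin (Cp, −5.16 ± 0.156), Cxcl15 (−4.96 ± 0.338), Col3a1, the membrane protease Mme (−4.54 ± 0.163), matrilin 2 (Matn2, −4.51 ± 0.117), Saa3 (−4.51 ± 0.432), Serpina3n (−4.50 ± 0.322), the matrix protease Mmp3 (−4.42 ± 0.267) and Dcn (−4.38 ± 0.235). Their adjusted p-values lay between 3.92e-07 and 0.000529. The VE-labelled arrays spread widely in Cxcl15, Saa3 and Mmp3 (SD 0.881, 1.15 and 0.686). Serpina3n belongs to a cluster of close paralogs and is uncertain for that reason.

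Of 39 cell cycle genes 0 rose and 38 fell, 0 and 39 adjusted over the list alone, with a median of −1.03 (camera adjusted p = 3.20e-38, and adjusted p = 0.135 with an estimated correlation). Mki67 fell by 1.54 ± 0.128, the mitotic kinase Melk by 1.5 ± 0.103, cyclin E1 (Ccne1) by 1.48 ± 0.172 and Ccna2 by 1.40 ± 0.139. Of 35 mesenchymal genes 0 rose and 22 fell, 0 and 23 adjusted over the list alone, with a median of −1.14 (camera adjusted p = 1.87e-22, and adjusted p = 0.125 with an estimated correlation). After Col3a1 and Dcn, Bgn fell by 3.89 ± 0.112 and Postn by 3.80 ± 0.135. Basement membrane and matrix genes gave 1 up and 11 down of 49, and 3 and 14 adjusted over the list alone (camera adjusted p = 0.000341, and adjusted p = 0.135 with an estimated correlation), with thrombospondin 1 (Thbs1) at −2.73 ± 0.186, Col12a1 at −1.96 ± 0.145 and tenascin C (Tnc) at −1.72 ± 0.151. Against the N-labelled line, this list was not called in either of the other lines: 11 up and 4 down in the VE-labelled line, 12 and 5 adjusted over the list alone (camera adjusted p = 0.165), and 6 up and 15 down in the VE+N-labelled line, the same adjusted over the list alone (camera adjusted p = 0.0828).

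Of 42 endothelial identity genes 14 rose and 2 fell, 21 and 2 adjusted over the list alone, with a median of 0.28 (camera adjusted p = 2.09e-08, and adjusted p = 0.258 with an estimated correlation). The water channel Aqp1 rose by 2.12 ± 0.157, Clec14a by 1.10 ± 0.122 and Myct1 by 0.96 ± 0.103, and the members that fell, named after their values were seen, were the transcription factor genes Ets1 at −0.67 and Fli1 at −0.40. Endothelial identity was the single list called higher, and 16 were called lower. Cholesterol synthesis genes gave 0 up and 12 down of 20, and 0 and 14 adjusted over the list alone (camera adjusted p = 6.02e-10, and adjusted p = 0.258 with an estimated correlation), with Cyp51 at −1.22 ± 0.175 and the pathway regulator Srebf2 at −1.04 ± 0.115. Interferon response genes gave 0 up and 12 down of 30, and 0 and 14 adjusted over the list alone (camera adjusted p = 1.76e-10, and adjusted p = 0.280 with an estimated correlation), with Rsad2 at −1.81 ± 0.132 and the chemokine Cxcl10 at −1.40 ± 0.134. Hypoxia and glycolysis genes gave 1 up and 15 down of 31, and 1 and 17 adjusted over the list alone (camera adjusted p = 1.21e-07, and adjusted p = 0.280 with an estimated correlation), with Ero1a at −1.49 ± 0.123 and the glycolytic enzymes Pfkp at −1.32 ± 0.123 and Hk2 at −1.29 ± 0.141.

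Signalling lists fell as well. Tip cell and VEGF pathway genes gave 2 up and 14 down of 36, and 3 and 16 adjusted over the list alone (camera adjusted p = 2.05e-07, and adjusted p = 0.280 with an estimated correlation), with angiopoietin 1 (Angpt1) at −2.48 ± 0.154 and the immediate early gene Egr1 at −1.43 ± 0.110. FGF pathway genes gave 3 up and 15 down of 33, and 4 and 15 adjusted over the list alone (camera adjusted p = 5.48e-07, and adjusted p = 0.135 with an estimated correlation), with the heparan sulfate carrier Sdc2 at −2.20 ± 0.121, Etv1 at −1.71 ± 0.126 and Dusp6 at −1.51 ± 0.129. Wnt/beta-catenin targets gave 0 up and 7 down of 28, the same adjusted over the list alone (camera adjusted p = 0.000613, and adjusted p = 0.280 with an estimated correlation), with Apcdd1 at −2.33 ± 0.216, the adhesion receptor Cd44 at −1.83 ± 0.112, Sox9 at −1.67 ± 0.144 and Myc at −1.37 ± 0.108. Against the N-labelled line these targets were not called, with 8 up and 3 down in the VE-labelled line, 9 and 4 adjusted over the list alone (camera adjusted p = 0.135), and 3 up and 8 down in the VE+N-labelled line, 4 and 8 adjusted over the list alone (camera adjusted p = 0.134). Arterial and Notch genes gave 3 up and 9 down of 30, and 3 and 10 adjusted over the list alone (camera adjusted p = 0.00762, and adjusted p = 0.280 with an estimated correlation), with Cxcl12 at −2.89 ± 0.112 and Notch2 at −1.51 ± 0.128.

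Inflammation genes gave 1 up and 8 down of 31, and 3 and 11 adjusted over the list alone (camera adjusted p = 0.000517, and adjusted p = 0.280 with an estimated correlation). Cxcl5 differed by −2.86 ± 0.217, Lcn2 by −2.74 ± 0.393 and the adhesion molecule Vcam1 by −2.66 ± 0.158. The SD between the VE-labelled arrays was 0.528 for Cxcl5 and 1.04 for Lcn2. Axon guidance and Eph genes gave 4 up and 18 down of 52, and 5 and 19 adjusted over the list alone (camera adjusted p = 0.000517, and adjusted p = 0.280 with an estimated correlation), with Sema5a at −2.90 ± 0.157 and Epha7 at −2.44 ± 0.158. Neural markers gave 0 up and 4 down of 20, the same adjusted over the list alone (camera adjusted p = 0.00138, and adjusted p = 0.280 with an estimated correlation), led by the adhesion gene Ncam1 at −2.76 ± 0.104. Mural cell genes gave 1 up and 5 down of 24, and 1 and 6 adjusted over the list alone (camera adjusted p = 0.0130, and adjusted p = 0.280 with an estimated correlation), with Pdgfrb at −4.30 ± 0.140 and Notch3 at −2.44 ± 0.106, while Anpep rose by 1.67 ± 0.107. The mural call was lost without VE+N replicate 2 (adjusted p = 0.187).

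TGF-beta and BMP targets gave 3 up and 8 down of 35, and 5 and 10 adjusted over the list alone (camera adjusted p = 0.0256, and adjusted p = 0.280 with an estimated correlation), with the BMP antagonist Grem1 at −3.09 ± 0.131, while Id2 rose by 1.32 ± 0.151. That call was lost without VE replicate 1 (adjusted p = 0.0689), without VE+N replicate 2 (adjusted p = 0.113) and without the dimmest 50% of genes (adjusted p = 0.0898). YAP/TAZ targets gave 1 up and 6 down of 22, and 4 and 8 adjusted over the list alone (camera adjusted p = 0.0434, and adjusted p = 0.280 with an estimated correlation), with F3 at −3.21 ± 0.143, Axl at −2.27 ± 0.138 and Ccn1 at −1.59 ± 0.157. This one was lost without VE replicate 2 (adjusted p = 0.0702), without VE+N replicate 1 (adjusted p = 0.164) and without the dimmest 25% of genes (adjusted p = 0.0836). Median centring raised every VE+N minus VE difference by 0.0879, which turned the medians of the axon guidance, mural, TGF-beta and YAP/TAZ lists from −0.0787, −0.0624, −0.0845 and −0.0122 to 0.00925, 0.0255, 0.00337 and 0.0757, with their camera calls still lower. It also moved the share of higher genes among those called from 42.3% to 60.8%, and among genes over 2-fold from 21.7% to 29.7%. The other 13 lists were not called, the lowest adjusted p being 0.108, and in 4 of them the median, the mean and the test differed in sign.

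**Figure D2:**
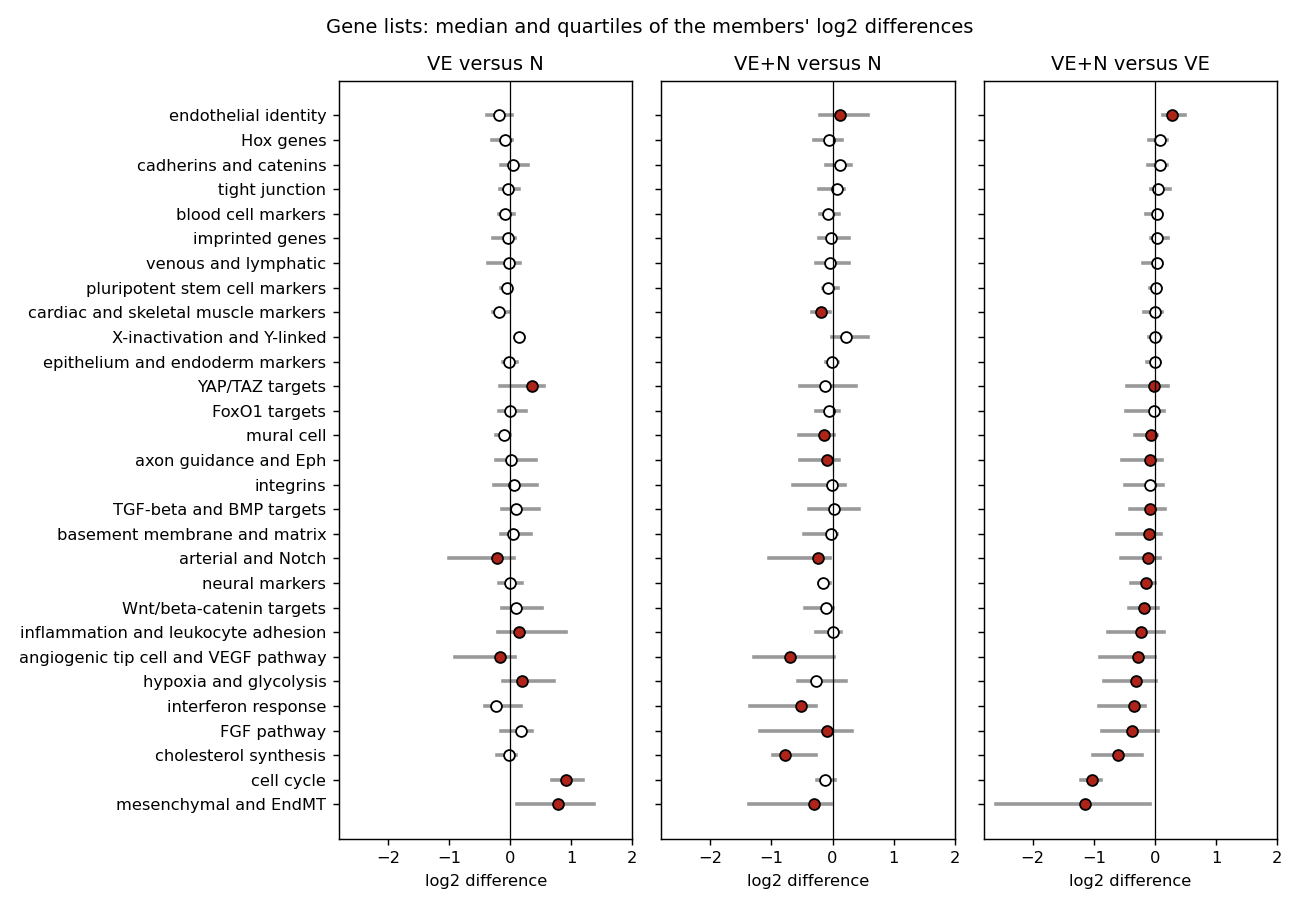
Median log2 difference (circle) and quartiles (grey line) over the measured members of 29 of the 30 gene lists in each comparison (x axis, log2), with filled red circles for a camera adjusted p below 0.05 at a preset correlation of 0.01. The cell cycle list had a median of 0.92 in VE versus N and −1.03 in VE+N versus VE, and the endothelial identity list 0.28 in VE+N versus VE.

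The position of the VE+N-labelled line between the others was described for the 760 genes that differed over 2-fold between the VE- and N-labelled lines. Of these, 307 (40.4%) differed from the N-labelled line and did not pass the test against the VE-labelled line, such as Gatm, Aplnr, Gja1 and Pmepa1. This class held 179 of 571 genes without the dimmest 50% of genes, and 541 of 995 with all probe sets tested. Another 175 (23%) differed from the VE-labelled line and did not pass against the N-labelled line, and 166 of these were higher in the VE-labelled line, such as Cxcl15, Saa3 and Col1a1. In 81 genes, such as Bgn, Fabp4 and Entpd1, the VE+N-labelled line lay between the others and differed from both. It lay beyond the VE-labelled line in 149, such as Rassf9, Igfbp5 and the stem cell factor receptor Kit, and beyond the N-labelled line in 39, such as Dpt, Mme and Dcn. The last 9 genes passed neither test. A test that was not passed does not show that 2 lines were alike.

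The calls of the VE- and VE+N-labelled lines against the same N-labelled arrays overlapped: 951 genes were higher in both and 938 lower in both, and 104 went opposite ways. Independent lists of these sizes would share 171 and 124. Across genes, which are not independent replicates, the differences correlated at r = 0.696, with a covariance of 0.167. Unchanged lines simulated against the same N-labelled arrays gave 0.50, which a shared line sets by itself, and 0.00854. These simulations hold no real differences, and a gene particular to the N-labelled line enters both comparisons. The 2 comparisons that share the VE+N-labelled line overlapped too, with 598 genes higher and 528 lower in both and 92 opposite. Independent lists would share 86.8 and 104 there (r = 0.516, simulated 0.501). In the 2 comparisons that share the VE-labelled line, opposite signs set this line apart from both others. There 775 genes went opposite ways, and 242 were higher and 144 lower in both (r = −0.256, simulated −0.499). The overlap by itself thus does not show a particular likeness of the VE- and VE+N-labelled lines. The N-labelled arrays were not split, since each part would hold 1 array, so part of the excess may come from these shared arrays. Across all 3 lines, 4457 genes passed limma's F test, 2866 or 2905 without N replicate 1 or N replicate 2, and 1732 in the methods' analysis of variance with Benjamini-Hochberg.

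Neighbouring genes on several chromosomes differed together, in a search that was chosen after the data were seen. The brighter 50% of genes were put in the order of the GRCm38.p6 annotation, and each of 20 chromosomes was searched for runs. Each chromosome's mean was taken off first, so the search does not see a shift of a whole chromosome. In VE versus N, chromosome 5 had a median of −0.174 (126 called lower, 55 higher) and chromosome 15 of 0.105 (17 lower, 64 higher). The median over all 9952 genes searched was −0.0246. The smallest p that 200 shuffles of gene order can give, 0.005 by permutation, was reached on chromosomes 4, 10, 13, 18 and 19 in VE versus N, on chromosomes 4, 6, 10, 13 and 18 in VE+N versus N, and on chromosome 4 in VE+N versus VE. The 4 runs described here were picked for their length and size, and their medians come from the data that set their ends. The genes that bound the runs are named as landmarks, outside the rule for named genes. On chromosome 10, 146 genes from Plekhg1 to Hk1 had a median log2 difference of −0.54 in the VE-labelled against the N-labelled line, with 96 called lower and 6 higher. The next 348 genes, from Supv3l1 to Olfr767, had medians of 0.33 in the VE-labelled and 0.54 in the VE+N-labelled line against the N-labelled line. On chromosome 18, 56 genes from Gramd3 to Smad4 had medians of −0.50 and −0.64 in these lines, and 83 genes at the end of chromosome 4 had medians of −0.18 (18 called lower, 5 higher) in the VE-labelled and −0.50 (56 lower, 4 higher) in the VE+N-labelled line. Several named genes lie in these runs, among them Gja1, Lilrb4a, Lilr4b, Plagl1, Myct1 and Sesn1 in the first part of chromosome 10, Rassf9, Stab2, Dcn, Nts, Ptprb, Dusp6, Gadd45b, Lss and Itga7 in the second, Pdgfrb and Apcdd1 on chromosome 18, and Ctnnbip1 on chromosome 4. With every gene of chromosomes 4, 10 and 18 left out, not only the runs, 7 list calls were lost and 2 gained. No other chromosomes were left out for comparison. In VE versus N the lost calls were the tip cell genes (median −0.173 to −0.148, adjusted p = 0.0596), the YAP/TAZ targets (0.365 to 0.365, adjusted p = 0.0596) and the arterial genes (−0.211 to −0.198, adjusted p = 0.0691). In VE+N versus N they were endothelial identity (0.116 to 0.0954, adjusted p = 0.0599) and the FGF pathway (−0.0837 to −0.0658, adjusted p = 0.0675). In VE+N versus VE they were the mural genes (−0.0624 to −0.057, adjusted p = 0.0768) and the TGF-beta and BMP targets (−0.0845 to −0.0658, adjusted p = 0.106). The losses do not show that the runs carried these lists.

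**Figure D3:**
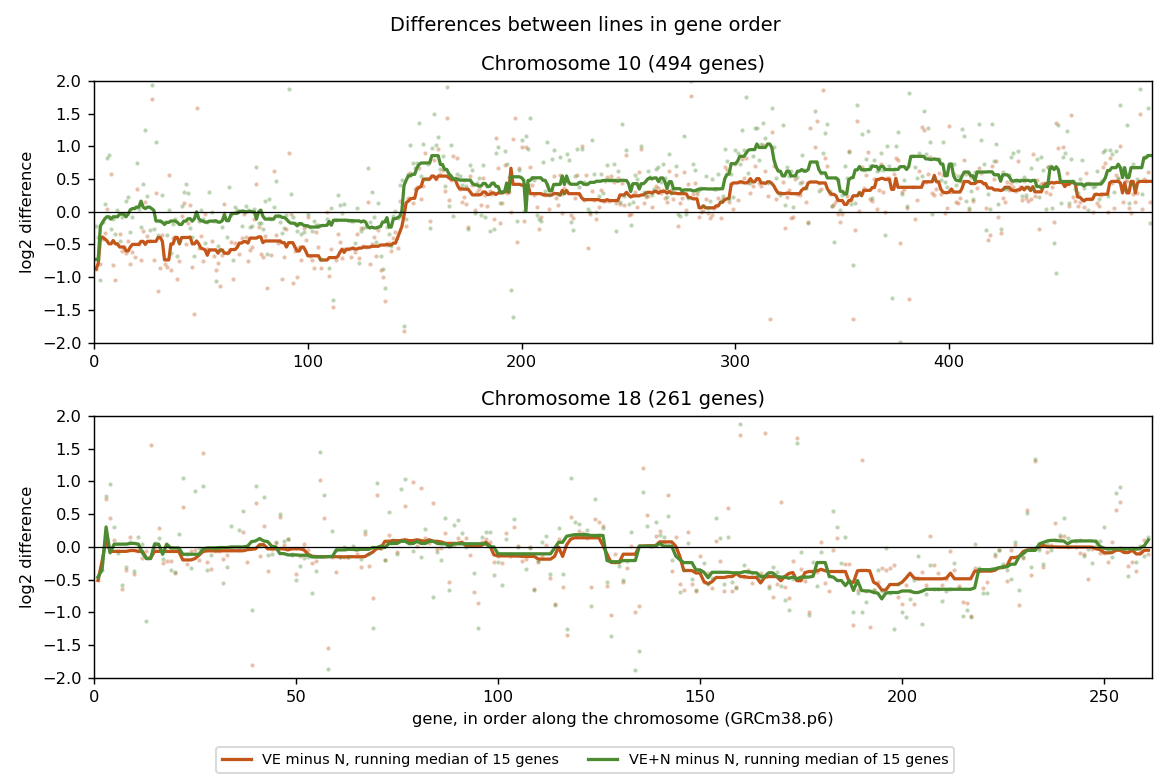
Log2 difference from the N-labelled line (y axis) of the VE-labelled (orange) and VE+N-labelled (green) lines for 494 genes of chromosome 10 and 261 genes of chromosome 18, in gene order (x axis), with points for genes, lines for running medians of 15 genes, and 20 and 9 points outside the axis limits. On chromosome 10 both lines step up after the first 146 genes, from −0.54 to 0.33 and from −0.14 to 0.54.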

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

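These tests of unnamed probe sets were chosen after the gene results were seen. Signal was found in the part of the arrays that the gene comparisons leave out. Of 13767 probe sets with no gene symbol or several, 173 passed adjusted p 0.05 and 2-fold in VE versus N, 242 in VE+N versus N and 71 in VE+N versus VE. The annotation names several genes for 1621 of the 13767 and no gene for 12146. No biological explanation was tested.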

How the results depend on the processing

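Named genes were mostly picked among called genes with the largest changes. That most of them passed and kept their direction was thus largely set by the choice. Of 376 differences of named genes 371 passed the test, and of 90 list tests 34. Only results that passed the main test could count as reversed, with lists judged by the direction of their test and not by their median. None of them reversed under the alternatives that covered it. Some list medians did change sign, such as those of the axon guidance, mural, TGF-beta and YAP/TAZ lists in VE+N versus VE with median centring. Calls of named genes were lost: 155 under the methods' analysis of variance with Benjamini-Hochberg, 108 under treat and 35 with all probe sets. Calls were also lost when 1 array was left out. Treat and that analysis gave no list tests, and removing the dimmest 50% of genes or chromosomes 4, 10 and 18 left 295 and 314 of the differences. Cdh5 in VE versus N, not passed in the main test, passed as lower in the VE-labelled line with median centring (−0.44), quantile normalization again (−0.39), the trended robust prior, the dimmest 50% of genes removed, and the methods' analysis of variance without adjustment.

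With an estimated correlation, which also brings the test down to 3 degrees of freedom, 0 list tests passed. With fry 55 passed, but fry asks whether a list changed at all and camera whether it changed more than other genes, so its count is no measure of the camera calls. The class of genes that differed from the N-labelled line and did not pass against the VE-labelled line held 307, and 179 when the dimmest 50% of genes were removed, with fewer genes tested. Testing all probe sets gave 541 in that class and 1117 calls in VE+N versus VE. The methods' analysis of variance without adjustment gave 4678 calls in VE versus N and 3996 in VE+N versus VE. With the authors' fold over 2 it gave 751, 909 and 493 in the 3 comparisons, where the main test gave 760, 918 and 502. After Benjamini-Hochberg the analysis of variance gave 1276, 1867 and 311 calls in the 3 comparisons, 138 over 2-fold in VE+N versus VE, and 1732 in its F test. It has fewer degrees of freedom because variances are not moderated. The stricter question of treat, a change over 1.5-fold, gave 590, 795 and 334 calls, and the 334 in VE+N versus VE were all over 2-fold. For the other moved values the cause was not tested.

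Leaving out 1 array gave 1688 (without VE replicate 2) to 3356 (without VE+N replicate 1) calls in VE versus N, 2243 (without N replicate 1) to 3800 (without VE+N replicate 1) in VE+N versus N, and 966 (without VE replicate 2) to 2049 (without VE+N replicate 1) in VE+N versus VE. The F test gave 2866 (without N replicate 1) to 4568 (without VE+N replicate 1). A line then has 1 array, and its spread is taken from the others.

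With the replicate block the counts were 3056, 3864 and 2055, of which 2897, 3661 and 1895 were shared with the main analysis. Deviations of same-numbered arrays correlated at −0.00504, 0.123 and 0.0689, and the labels give equal numbers no further meaning, so a shared day or batch is neither shown nor excluded. Probe sequences were not used, so signal over background and GC content were not examined.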

Other observations

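The tests of the 3 patterns weighed below were all chosen after the results were seen. Some fixed lists were called in no comparison, yet held members with large differences. The Hox gene Hoxd10, a marker of position along the body, was lower than in the N-labelled line by a log2 difference of −2.07 in the VE-labelled and −2.20 in the VE+N-labelled line. Hoxa2 was higher in the VE+N-labelled line, by 1.40 against N and 0.80 against VE. Among imprinted genes, Mest differed from the N-labelled line by −4.39 in the VE-labelled and −4.25 in the VE+N-labelled line, and the growth factor Igf2 by −1.78 and −2.24. The growth regulator Plagl1 was higher by 1.73 and 1.94. The Y-linked genes Uty and Eif2s3y were higher in the VE-labelled line by 1.05 and 0.86, and in the VE+N-labelled line by 0.95 and 1.02.

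Among integrins, the collagen receptor Itga2 was lower in the VE- and VE+N-labelled lines by −2.85 and −2.59, and Itga8 was higher in the VE+N-labelled line by 3.92. The FoxO1 targets Angpt2 and Bcl2l11 were lower in the VE-labelled than in the N-labelled line by −1.50 and −1.66. Among partners of cadherins, the catenin-like gene Ctnnal1 was higher by 1.29 in the VE-labelled and 2.43 in the VE+N-labelled line. A run of 19 genes on chromosome 13, bounded by the histone genes H2bc14 and H2ac1 (named as landmarks, outside the rule for named genes), had a median of 1.12 in VE versus N, with 13 called higher and 0 lower (p = 0.005 by permutation, the smallest that 200 shuffles give). Histone copies are near-identical, and which copy a probe set reads is uncertain.

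The first pattern is the runs of neighbouring genes on chromosomes 4, 10 and 18. In the comparison with the largest median for each of the 4 runs, the smallest median in size without genes changed over 2-fold was 0.48. A few strong genes can hardly set a median over 56 to 348 genes. That removal was thus bound to change little and is no test of such genes as the cause. In the same comparisons single arrays or extracts are excluded: the largest run median between 2 arrays of 1 line was 0.105, and every pairing of arrays between lines gave at least 0.495. In 2 of the other 8 comparisons of these runs they stay open, with medians of −0.138 (first part of chromosome 10, VE+N versus N) and −0.0904 (chromosome 18, VE+N versus VE) against 0.123 and 0.105 within a line. A difference in DNA copy number would move most genes of a run the same way. At least 89% did in the comparisons with the largest medians, but the ends of the runs were set on these same data. That share was thus largely set by the choice and is no test of copy number. In the other comparisons of the runs it ran from 64.3% to 91.6%. No DNA measurement was used and no biological explanation was tested, so a difference in copy number stays open.

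The second pattern is the higher mesenchymal genes in the VE-labelled line. The list median, 0.784 in the main test, stayed at 0.676 or more under both other scalings. Median centring takes the same 0.108 off every difference, so a shift of that size does not make the list median. Quantile normalization again repeats a step of RMA. Neither starts from the probe values, so other effects of the authors' scaling are not excluded. Mesenchymal cells mixed into the VE-labelled extracts could not be told from a change in the cells themselves: of 12 members below the median gene in the N-labelled line 6 (50%) were higher, Fap was lower and 5 did not pass. The labels offer the cadherin as a biological explanation, and 1 line per state cannot separate it from other differences between the lines.

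The third pattern is that Cdh5 did not differ as the labels name the cadherins: it missed the threshold in the main test, and where VE versus N passed, under 5 alternatives, it was lower in the VE-labelled line (−0.44 with median centring). That direction goes with exchanged labels of the N- and VE-labelled arrays, but Cdh2 differed by −1.80 in the direction the labels name. This argues against an exchange only if the Cdh2 signal reads the N-cadherin of the labels, which was not tested. A probe set at its floor stays open: Cdh5 lay at or above the 64.3 percentile of genes in every line, but a rank among other probe sets does not show its own background. A transcript of an altered or added allele read by the same probe set stays open too, since the only difference available is the −0.34 of 1 probe set.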
